A study of Homo sapiens with 7 samples.

How the data were processed

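Gene expression was measured in CD8 T cells sorted from the blood of healthy donors, on 7 Affymetrix genome-wide expression arrays of 54675 probe sets each. Per the labels' protocols, naive cells were gated as CD45RA positive and effector memory (EM) and central memory (CM) cells as CD45RO positive, with a further surface marker in each gate. T side population (TSP) cells, which pump out the dye Hoechst, were gated as CD3 and CD8 positive and low in dye, with no gate on CD45RA, CD45RO or that marker. TSP cells were incubated with the dye for 90 minutes at 37 °C and then stained with antibodies for 30 minutes on ice, whereas the other subsets were only stained on ice. There were 2 naive, 2 EM, 2 TSP and 1 CM array, and the labels do not say that replicates came from separate donors. The p-values therefore measure the spread between these samples, which may be technical.

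The deposited table holds log values, read here as log2, that the authors made with GeneSpring GX 12.5, per the submitters' processing notes. The base of the logarithm and the background correction and normalization method are not given in the sources used here. Base 2 was taken because the largest range of a probe set over the arrays, 9.42, exceeds a scanner's range on a base of 10. The median over the 7 arrays was exactly 0 in all 54675 probe sets, so each probe set had been centred and the table gives differences between arrays but no levels. Each array's median over all probe sets was also 0. In 45.9% of probe sets 2 or more arrays held exactly 0, and such ties narrow the spread within a group. A filter on dim probe sets and a trend of the variance with intensity need levels and were not run.

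Probe sets were named through the platform annotation, checked by Entrez identifier against the RefSeq gene table for the 41037 that matched. There were 41091 probe sets with 1 gene symbol, 1801 with several and 11721 with none, besides 62 control probe sets, and genes were named only from the first kind. Genes without such a probe set, among them TCF7, EGR2 and PDCD1, were not analysed here, and XIST, TSIX and Y-linked genes were left out. The mean of a gene's probe sets was used, which gave 19724 genes from 41001 probe sets. Several probe sets stood behind 10501 genes, and their range is given beside ABCG1, ABCA1, NR4A1, RGS16, ACTN1 and ITGA1, whose probe sets were far apart.

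Group means were fitted to all 7 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with 3 residual and 2.14 prior degrees of freedom. The lone CM array was assumed to vary like the other groups. Each of the 6 comparisons used a Benjamini-Hochberg adjusted p under 0.05 over 19724 genes. Values are log2 differences of group means with the standard error (SE) of the fit. The small number of arrays limits the precision, though not alone, since counts also moved with the normalization and the probe sets used. In simulated data with 200 changed genes among 19724, the test for TSP against naive recovered 57.1%, 94.9% and 99.7% of genes changed by 1, 2 and 4 on the log2 scale, and 6.03% of its calls were false. The simulated genes varied independently, with normal noise at each gene's fitted spread. These rates therefore leave out correlation between genes and differences between sets of arrays, and may not hold for the real arrays.

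Before the data were examined, 34 gene lists of pathways and cell type markers were written from general knowledge. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 204 tests. With the correlation estimated from the residuals, no list passed in any comparison, so that second p is given beside each call. In simulated data a list of 28 genes shifted by 1 was called in 20 of 20 datasets for TSP against naive, and 2 of 580 tests of unshifted lists were called. Genes were independent in these data, so this cannot favour the preset over the estimated correlation. Lists share members, and 17 of the 31 measured MAIT cell markers also stood in another list.

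The genes named were fixed by a rule before the data were examined. Per comparison, it takes the 10 higher and 10 lower genes with the largest differences among those past the threshold whose arrays did not overlap, up to 4 members of each list by size of difference, and a fixed set around NR4A1, the dye-exporting transporters and residency and MAIT markers. Donor-variable families such as HLA, KIR and receptor segments were not named under the first part. GZMA, CTSH, IRF4 and BCL11B in TSP against naive, ID3, ZFP36 and EOMES in TSP against EM, and CCR2 and ME1 in EM against naive, were chosen after their values were seen, to complete small counts. The same holds for HSPA2 in TSP against naive and MCM3.

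The spiked hybridization controls split the arrays into a set with low values (EM replicate 1, CM, TSP replicate 1) and a set with high values (both naive arrays, EM replicate 2, TSP replicate 2). This set was used as a block and for differences within a set, an alternative chosen after seeing the data. The other alternatives were quantile normalization, the most variable probe set of each gene, all probe sets, fits of only the groups compared, a block on replicate number, a robust prior, thresholds with a 2-fold minimum, and leaving out each array in turn.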

Results

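The series measured gene expression in 4 subsets of human blood CD8 T cells, with 2 naive, 2 EM, 1 CM and 2 TSP arrays. TSP cells are those that export Hoechst dye, a property given by ATP-binding cassette (ABC) transporters. The study asked how these cells relate to resident memory T cells and to the nuclear receptor NR4A1. All values below are log2 differences between subsets, because the table holds no expression levels. Incubation in dye at 37 °C was part of the TSP preparation alone.

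TSP cells differed from naive cells most in immediate-early genes, which are induced within minutes of a stimulus, and in genes of innate-like and effector T cells. EGR3 and EGR1, zinc finger transcription factors induced by T cell receptor signals, were higher by 8.13 ± 0.32 (SE, n = 2 and 2 arrays; limma adjusted p = 0.00877) and 6.52 ± 0.28 (adjusted p = 0.00877). The nuclear receptor NR4A2 was higher by 5.79 ± 0.78 (adjusted p = 0.0364), and IER3 by 4.69 ± 0.26. Among secreted proteins, the chemokines CCL20 and CCL4 were higher by 7.94 ± 0.83 and 7.50 ± 0.48, and TNF by 7.03 ± 0.47. The C-type lectin KLRB1, which encodes CD161, was higher by 7.07 ± 0.70 and the interleukin-18 receptor subunit IL18RAP by 5.54 ± 0.28. TUBB2A, a tubulin, was higher by 6.05 ± 0.84.

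Of 28 measured immediate-early genes 10 were higher and 0 lower in TSP than naive cells, with 21 higher adjusted over the list alone. The list median was 1.62 (camera adjusted p = 3.38e-15, and adjusted p = 0.496 with an estimated correlation), and 1.55 between the arrays of the high hybridization-control set. Of 31 MAIT cell markers 10 were higher, or 24 adjusted over the list alone, with a median of 2.22 (adjusted p = 4.25e-16, and adjusted p = 0.582 with an estimated correlation). They included KLRB1, IL18RAP, IL18R1 at 3.01 ± 0.34 and the activating receptor NCR3 at 3.19 ± 0.23. The transcription factor ZBTB16 at 3.42 ± 0.60 did not pass (adjusted p = 0.0596), and the MAIT-associated transporter SLC4A10 differed by -0.04 ± 0.15 (adjusted p = 0.926). Type 17 genes had 5 of 26 higher, CCL20, KLRB1, the receptor kinase LTK at 4.04 ± 0.58, CTSH and IRF4, and 11 adjusted over the list alone (median 1.33, adjusted p = 1.16e-08, and adjusted p = 0.496 with an estimated correlation).

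Cytotoxic effector genes had 4 of 37 higher in TSP than naive cells: CCL4, TNF, FASLG at 5.17 ± 0.43 and GZMA at 4.56 ± 0.41. Adjusted over the list alone 23 were higher, with a median of 1.80 (adjusted p = 1.84e-14, and adjusted p = 0.600 with an estimated correlation). The median was 1.15 without naive replicate 1. IFNG at 5.03 ± 1.59 and GZMB at 2.55 ± 1.23 did not pass (adjusted p = 0.195 and 0.385). IFNG was at 2.50 without TSP replicate 1 and at 7.57 without TSP replicate 2, where it passed (adjusted p = 0.0176), and GZMB at 0.74 and 4.36, where it did not. In the NF-kB pathway list 7 of 27 genes were higher, among them the kinase MAP3K8 at 3.72 ± 0.43, with 9 adjusted over the list alone (median 0.46, adjusted p = 5.34e-05, and adjusted p = 0.516 with an estimated correlation). Without TSP replicate 2 that median was 0.82. Among p53 target genes 3 of 25 were higher, GADD45A at 4.23 ± 0.27, CDKN1A at 3.42 ± 0.31 and PLK2 at 3.42 ± 0.35, which act in growth arrest and stress responses. Adjusted over the list alone 7 were higher and 1 lower, and the list had a median of 0.44 (adjusted p = 0.00186, and adjusted p = 0.496 with an estimated correlation). The median was 0.28 without TSP replicate 1, 0.20 without naive replicate 1 and 0.25 with the hybridization-control block, still called in each.

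Of 40 genes associated with naive T cells 9 were lower and 0 higher in TSP than naive cells, and 19 lower adjusted over the list alone (median -1.06, adjusted p = 1.14e-13, and adjusted p = 0.496 with an estimated correlation). The lymph node homing receptor CCR7 was lower at -2.53 ± 0.35, ROBO1 at -3.14 ± 0.27 and OXNAD1 at -1.93 ± 0.28. Outside the lists, the zinc finger gene ZNF658 differed by -3.39 ± 0.23, WDR5B by -2.98 ± 0.19, GIMAP4, a GTPase of lymphocytes, by -2.92 ± 0.28 and the translation termination factor GSPT2 by -2.75 ± 0.15. Genes of T cell identity had SH2D1A higher at 1.66 ± 0.24 and LAT, THEMIS and BCL11B lower, at -1.19 ± 0.15, -1.06 ± 0.13 and -1.01 ± 0.12, with 1 of 19 higher and 5 lower adjusted over the list alone and no call for the list (median -0.03, adjusted p = 0.163).

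Among 43 ABC transporters, ABCG1 and ABCA1, both exporters of cholesterol and phospholipids, were higher in TSP than naive cells and 0 were lower, also adjusted over the list alone. ABCG1 differed by 1.89 ± 0.27 (adjusted p = 0.0416; probe sets 0.41 to 2.64) and ABCA1 by 1.11 ± 0.16 (adjusted p = 0.0429; probe sets 0.06 to 2.26). With the hybridization-control set as a block, neither passed (adjusted p = 0.0781 and 0.0634). The dye exporters ABCB1 at 0.69 ± 0.37 (adjusted p = 0.433) and ABCG2 at 1.00 ± 0.39 (adjusted p = 0.282) did not pass, nor did ABCC1 at -0.72 ± 0.20, and the list had no call (median 0.09, adjusted p = 0.194). The arrays differed: ABCB1 was at 1.24 without TSP replicate 1 and 0.15 without TSP replicate 2, and ABCG2 at 0.51 and 1.495, none past the threshold. NR4A1 itself differed by 1.73 ± 0.40 (adjusted p = 0.106), with probe sets from 0.20 to 2.98. Without TSP replicate 2 it was 2.35 and passed (adjusted p = 0.0315), and without TSP replicate 1 it was 1.10 and did not (adjusted p = 0.0544). NR4A3 at 3.84 ± 0.67 fell short in the fit of all arrays (adjusted p = 0.0594), but passed without TSP replicate 1 at 2.78 (adjusted p = 0.0445) and without TSP replicate 2 at 4.90 (adjusted p = 0.0226).

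Among residency genes, CD69, an early activation and retention marker, was at 1.88 ± 0.36 (adjusted p = 0.0687) and the integrins ITGAE and ITGA1 were at 0.50 ± 0.20 and 0.49 ± 0.21, neither past the threshold. Without TSP replicate 1 they were at 0.71 and 0.72 and without TSP replicate 2 at 0.29 and 0.25, and the probe sets of ITGA1 ran from -0.04 to 1.30. The chemokine receptor CXCR6 was at 2.85 ± 0.94 (adjusted p = 0.210), and at 3.90 with the hybridization-control block (adjusted p = 0.0180). Genes higher in resident memory cells had 1 of 33 past the threshold, CCL4, and 7 adjusted over the list alone, with a median of 0.43 (adjusted p = 0.00213, and adjusted p = 0.600 with an estimated correlation). The median was 0.07 without TSP replicate 1 and 0.74 without TSP replicate 2. The same list was not called between TSP and EM cells (median 0.07, adjusted p = 0.979) or TSP and CM cells (median 0.15, adjusted p = 0.369), where it was called without TSP replicate 2 (median 0.15, adjusted p = 0.0377). It was called higher in EM than naive cells (median 0.58, adjusted p = 2.88e-05, and adjusted p = 0.600 with an estimated correlation), with 1 of 33 past the threshold and 2 adjusted over the list alone. So it was in CM than naive cells (median 0.36, adjusted p = 0.00714, and adjusted p = 0.617 with an estimated correlation), with 0 and 0. The call for CM was lost with the hybridization-control block (median 0.03, adjusted p = 0.0894). Of 25 genes lower in resident memory cells, CCR7 and S1PR4, at -1.78 ± 0.26, were lower in TSP than naive cells. The egress receptor S1PR1 at -0.96 ± 0.24 and KLF2 at -0.29 ± 0.15 did not pass. Adjusted over the list alone 6 were lower and 2 higher, and the list had no call (median -0.20, adjusted p = 0.0544). It had one with the hybridization-control block (median -0.39, adjusted p = 0.0258), without TSP replicate 1 (-0.47, adjusted p = 0.0381) and without naive replicate 1 (-0.52, adjusted p = 0.00468). Without TSP replicate 2 the median was -0.04 and without naive replicate 2 it was 0.03, with no call in either. CD3E, CD8A and MKI67 differed by -0.08 ± 0.24, 0.16 ± 0.10 and -0.02 ± 0.10, none past the threshold, and CD8B by -0.80 ± 0.15 (adjusted p = 0.0654). Monocyte markers had 0 of 22 genes past the threshold and a median of 0.68 (adjusted p = 0.00083, and adjusted p = 0.641 with an estimated correlation). The median was 0.27 with the hybridization-control block, and there was no call without TSP replicate 1 (median 0.17, adjusted p = 0.0547). Their median was 1.00 in TSP replicate 1 and 0.02 in TSP replicate 2, against -0.21 to 0.10 in the other arrays, and 3' minus 5' control probe sets stood at 0.51 and -0.29 for GAPDH and 0.80 and -0.997 for ACTB in the same TSP arrays. In the others they ranged from -0.29 to 0.30 for GAPDH and from -1.09, in EM replicate 2, to 0.20 for ACTB. NK cell markers had 1 of 13 higher, NCR3, and 2 adjusted over the list alone, with a median of 1.29 (adjusted p = 0.000151, and adjusted p = 0.600 with an estimated correlation). The median was 0.70 without TSP replicate 1, 1.97 without TSP replicate 2 and 0.61 with the block.

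In all, 498 genes passed between TSP and naive cells, 245 higher and 253 lower in TSP, against 170 higher and 105 lower after quantile normalization. Of the 34 gene lists 14 passed, 13 higher and 1 lower. With the hybridization-control set as a block there were 287, 152 higher and 135 lower, of which 201 were among the 498, and within the 4 arrays of the high set limma called 0. The count was 0 without naive replicate 1 or 2, 1 without EM replicate 1 or 2, 62 without TSP replicate 1 and 98 without TSP replicate 2. Of the genes above, TUBB2A, IL18R1, IRF4, MAP3K8, SH2D1A, BCL11B, S1PR4, ABCG1 and ABCA1 did not pass with the block (adjusted p from 0.0507 to 0.0836). CCL20, KLRB1, LTK, OXNAD1, LAT, THEMIS and, again, MAP3K8, SH2D1A, BCL11B, S1PR4, ABCG1 and ABCA1 did not pass after quantile normalization (adjusted p from 0.0535 to 0.0906).

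**Figure D1:**
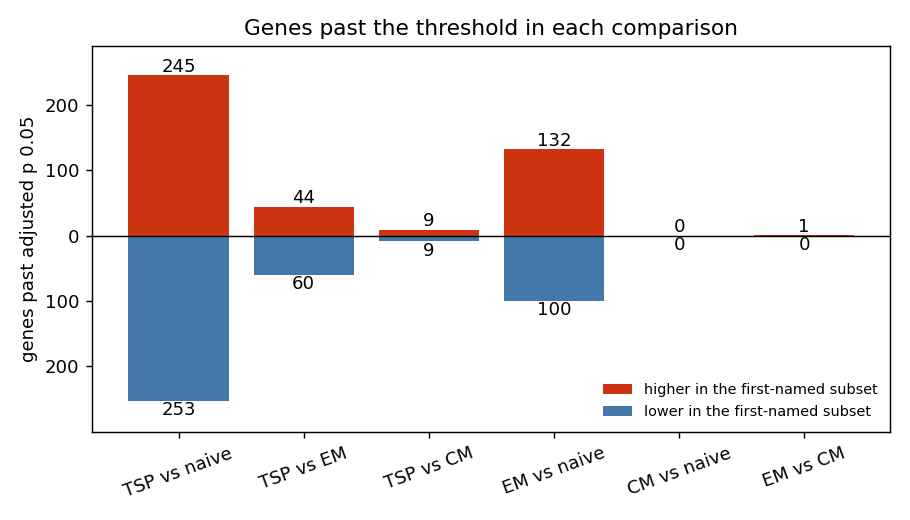
Bars give the number of genes past an adjusted p of 0.05 in each of the 6 comparisons, upward for genes higher and downward for genes lower in the subset named first. TSP against naive gave 245 and 253 genes, EM against naive 132 and 100, and CM against naive 0.

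TSP cells were then compared with EM cells, an antigen-experienced subset. Immediate-early genes again led: EGR1 was higher in TSP cells by 5.50 ± 0.28 (SE, n = 2 and 2 arrays; limma adjusted p = 0.0179), EGR3 by 5.18 ± 0.32 (adjusted p = 0.0287), the kinase SGK1 by 3.95 ± 0.24 and IER3 by 3.17 ± 0.26. With ZFP36, an mRNA-destabilizing protein, at 1.32 ± 0.14, they made 5 of 28 list members higher and 0 lower, or 18 higher adjusted over the list alone. The median was 1.19 (adjusted p = 2.21e-11, and adjusted p = 0.496 with an estimated correlation), and within the low and the high hybridization-control set it was 1.21 and 1.16. NR4A2 at 4.03 ± 0.78, NR4A3 at 3.29 ± 0.67 and NR4A1 at 1.59 ± 0.40 did not pass (adjusted p = 0.112, 0.126 and 0.183). NR4A3 passed without TSP replicate 2, at 4.36 (adjusted p = 0.0312), but not without TSP replicate 1, at 2.23 (adjusted p = 0.0704). NR4A1 was at 0.96 without TSP replicate 1 and at 2.21 without TSP replicate 2, past the threshold in neither.

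Naive-associated genes were also higher in TSP than EM cells. The bone morphogenetic protein antagonist NOG was higher by 5.27 ± 0.21 (adjusted p = 0.0143), LRRN3 by 4.88 ± 0.42, SCML1 by 3.66 ± 0.35 and the transcription regulator ID3 by 2.47 ± 0.24. These were the 4 of 40 past the threshold, with 0 lower, and adjusted over the list alone 17 were higher and 2 lower. The list had a median of 0.76 (adjusted p = 1.27e-10, and adjusted p = 0.496 with an estimated correlation), and 0.96 and 0.64 within the low and high sets. CCR7 at 2.11 ± 0.35 missed the threshold (adjusted p = 0.0889) and passed with the hybridization-control block (adjusted p = 0.0414).

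Cytotoxic genes lay lower in TSP than EM cells, with a list median of -0.71 (adjusted p = 0.000325, and adjusted p = 0.641 with an estimated correlation). The median was -1.12 without TSP replicate 1. Of 37 members 1 was lower, the T-box factor EOMES at -1.71 ± 0.16, and adjusted over the list alone 1 was lower and 1 higher. The granzymes GZMH at -4.30 ± 1.28 and GZMB at -2.93 ± 1.23, and FGFBP2 at -3.85 ± 1.40, did not pass, and the GZMB difference was -1.40 within the low and -4.46 within the high set. Without TSP replicate 1 GZMH and FGFBP2 were at -6.06 and -5.81, and without TSP replicate 2 at -2.53 and -1.90, none past the threshold. T cell identity genes had a median of -0.28 (adjusted p = 0.000118, and adjusted p = 0.496 with an estimated correlation), with THEMIS alone past the threshold of 19, at -1.39 ± 0.13, and 5 lower adjusted over the list alone. Without TSP replicate 1 their median was -0.42. Other genes lower in TSP than EM cells were TMCC3 at -3.78 ± 0.42, SETBP1 at -3.15 ± 0.26, the costimulatory receptor TNFRSF9 at -2.69 ± 0.25, FCRL3 at -2.63 ± 0.18 and GIMAP4 at -2.58 ± 0.28. Among those higher were the chaperone HSPA2 at 4.40 ± 0.18, PLK2 at 3.50 ± 0.35 and LTA at 2.27 ± 0.21.

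ABC transporters had no member past the threshold between TSP and EM cells, with 2 higher and 3 lower adjusted over the list alone, and a list median of 0.11 (adjusted p = 0.152). ABCG1 was at 1.56 ± 0.27 (adjusted p = 0.0940), ABCB1 at 0.77 ± 0.37 and ABCG2 at 0.69 ± 0.39, and without TSP replicate 1 and 2 in turn ABCB1 was at 1.31 and 0.23 and ABCG2 at 0.20 and 1.19. MAIT cell markers, which were higher in both TSP and EM than in naive cells, had a median of 0.70 between TSP and EM (adjusted p = 0.00213, and adjusted p = 0.670 with an estimated correlation). That call was lost without EM replicate 1 (median 0.34, adjusted p = 0.345) and without TSP replicate 2 (0.23, adjusted p = 0.573), and the median was 1.18 without TSP replicate 1. None of the 31 passed, 3 did so adjusted over the list alone, and KLRB1 was at 1.34 ± 0.70 (adjusted p = 0.484). Glycolysis genes had a median of 0.40 (adjusted p = 0.000759, and adjusted p = 0.496 with an estimated correlation) with 0 of 23 past the threshold, also adjusted over the list alone. Without TSP replicate 1 this was 0.26. Monocyte markers stood 0.52 higher (adjusted p = 0.00653, and adjusted p = 0.692 with an estimated correlation), 0.81 within the low set that holds TSP replicate 1 and 0.29 within the high set. They had no call without TSP replicate 1 (median 0.03, adjusted p = 0.256) or EM replicate 2 (0.27, adjusted p = 0.107), and stood at 1.00 without TSP replicate 2 and 0.89 without EM replicate 1.

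Altogether 104 genes differed between TSP and EM cells, 44 higher and 60 lower in TSP. With the hybridization-control block there were 65, 30 higher and 35 lower, 43 of them shared, and within the high set limma called 0. The count was 0 without naive replicate 1, naive replicate 2 or EM replicate 2, 2 without EM replicate 1, 2 without TSP replicate 1 and 12 without TSP replicate 2. LRRN3, SCML1, ID3, ZFP36, EOMES, PLK2 and TMCC3 did not pass with the block (adjusted p from 0.0505 to 0.0575), and IER3, PLK2, GIMAP4, THEMIS and LTA did not after quantile normalization (adjusted p up to 0.0804).

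**Figure D2:**
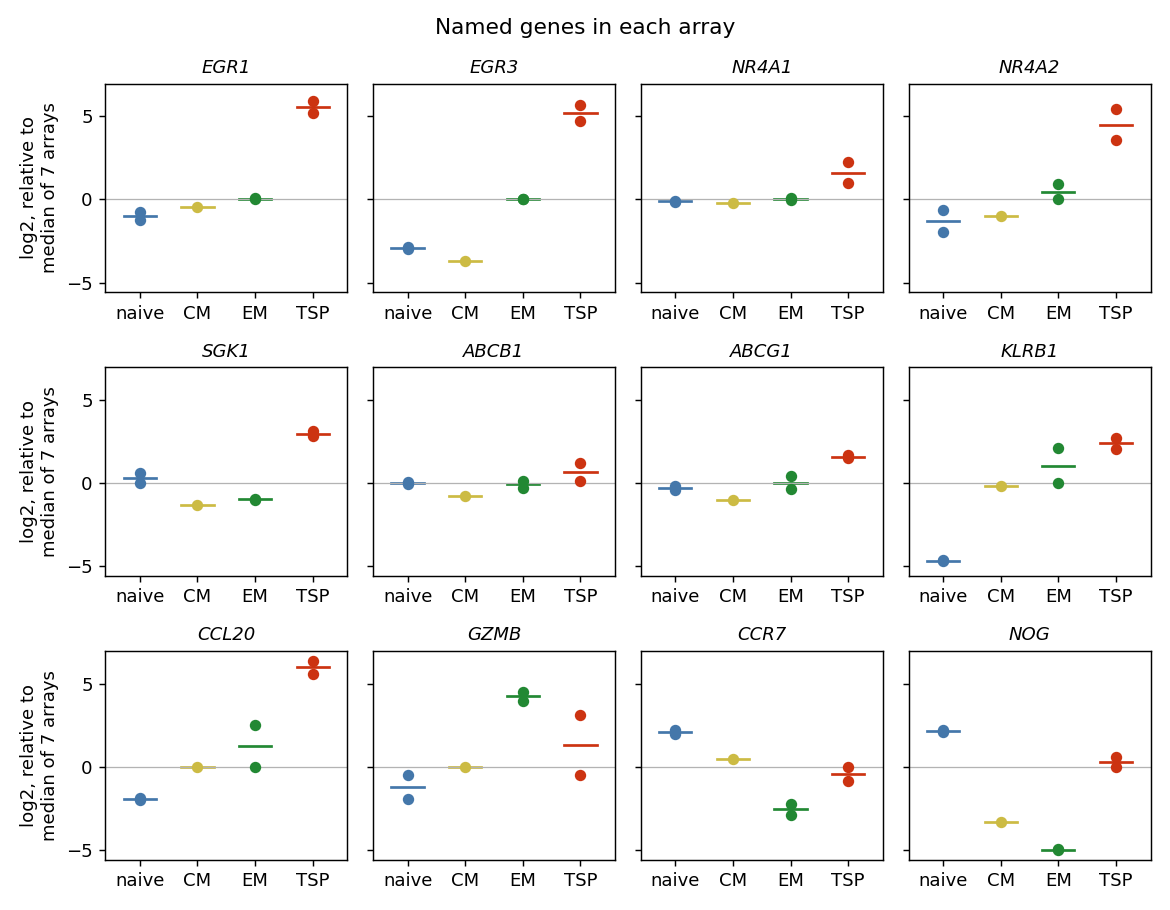
Each panel shows a gene's value in every array, on a log2 scale relative to the median of the 7 arrays, with a line at each subset's mean. EGR1, EGR3 and SGK1 were higher in both TSP arrays than in all others, whereas NOG and CCR7 in TSP lay between naive and EM cells.

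Against the lone CM array, EGR3 was again the most raised gene, at 8.93 ± 0.39 (SE, n = 2 and 1 arrays; limma adjusted p = 0.0230), with EGR1 at 6.01 ± 0.34, HSPA2 at 4.29 ± 0.22, SGK1 at 4.27 ± 0.29 and IER3 at 4.18 ± 0.31. The phosphatase DUSP5, which acts on ERK kinases, was higher in TSP cells by 4.02 ± 0.16, NOG by 3.59 ± 0.26, SPRY1, an inhibitor of receptor signalling, by 2.39 ± 0.19 and RGS16 by 1.93 ± 0.13, its probe sets ranging from -0.08 to 3.71. The 9 lower genes were GSPT2, WDR5B and FCRL3, all at -3.02, TIGD2 at -2.97 ± 0.22, ZNF623 at -2.31 ± 0.12, OXLD1 at -2.07 ± 0.14, DCP1B at -1.98 ± 0.14 and ZSCAN26 at -1.66 ± 0.13, with 1 receptor segment gene that is not named. Immediate-early genes had 4 of 28 higher, or 17 adjusted over the list alone, and a median of 1.17 (adjusted p = 5.81e-13, and adjusted p = 0.496 with an estimated correlation). Interferon-stimulated genes had a median of 1.11 (adjusted p = 2.68e-05, and adjusted p = 0.625 with an estimated correlation) with 0 of 33 past the threshold, also adjusted over the list alone. The CM array stood lowest for this list, at -0.68, against 0.28 and 0.13 in TSP and -0.495 to 0.36 in the naive and EM arrays. Against naive and EM cells the list had no call (median 0.43, adjusted p = 0.275, and median 0.32, adjusted p = 0.328). With the hybridization-control block it had one against naive cells (adjusted p = 0.0133). Monocyte markers stood 0.75 higher in TSP than CM cells (adjusted p = 0.000759, and adjusted p = 0.641 with an estimated correlation), and 1.24 within the low set, which compares TSP replicate 1 with CM, with 0 of 22 past the threshold, also adjusted over the list alone. There was no call without TSP replicate 1 (median 0.19, adjusted p = 0.0807). Genes lower in resident memory had a median of -0.64 (adjusted p = 5.41e-05, and adjusted p = 0.600 with an estimated correlation), with 0 of 25 past the threshold and 5 lower adjusted over the list alone. Their median was -0.28 without TSP replicate 2. The CM array itself lay above naive cells for this list, with a median of 0.57. Against EM cells the list was also called lower in TSP (median -0.32, adjusted p = 0.000526, and adjusted p = 0.600 with an estimated correlation). There 1 of 25 was lower and 0 higher, or 3 lower and 1 higher adjusted over the list alone. Against CM cells, KLF2, a regulator of tissue egress, was at -1.41 ± 0.19 and S1PR1 at -1.53 ± 0.29 (adjusted p = 0.0773 and 0.125). ABCB1 at 1.47 ± 0.46, ABCG2 at 1.45 ± 0.48 and NR4A1 at 1.86 ± 0.49 did not pass, also without TSP replicate 1, at 2.01, 0.95 and 1.24, or without TSP replicate 2, at 0.92, 1.94 and 2.48. These 18 genes, 9 higher and 9 lower, fell to 0 with the hybridization-control block, to 0 without any naive or EM array, to 1 without TSP replicate 1 and to 2 without TSP replicate 2. After quantile normalization there were 32, without HSPA2 and DUSP5 (adjusted p = 0.0545 and 0.0581).

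TSP cells differed the same way from all 3 other subsets in 14 genes. EGR1, EGR3, HSPA2, IER3, RGS16, SGK1 and SPRY1 were higher, and DCP1B, GSPT2, OXLD1, TIGD2, WDR5B, ZNF623 and ZSCAN26 were lower. HSPA2 was higher than in naive cells by 4.45 ± 0.18. The 3 comparisons share the TSP arrays: 50 simulated datasets with no group effect gave at most 0 such genes, a test that calls almost no gene to begin with. Independent lists of these sizes would share 0.000249 higher and 0.000351 lower, a value that leaves out the shared arrays. With 2 TSP arrays these cannot be split, so part of the overlap may come from them. The overlap was 0 with the hybridization-control block and without any naive or EM array, 1 without TSP replicate 1 and 2 without TSP replicate 2.

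EM cells were compared with naive cells as the reference for memory differentiation. NOG was lower in EM cells at -7.13 ± 0.21 (SE, n = 2 and 2 arrays; limma adjusted p = 0.00388), LRRN3 at -6.15 ± 0.42, CCR7 at -4.64 ± 0.35, the membrane protein MAL at -4.63 ± 0.56 and SCML1 at -4.49 ± 0.35. ACTN1 was lower at -3.59 ± 0.34, with probe sets from -6.32 to -0.05. Of 40 naive-associated genes 16 were lower and 0 higher, and adjusted over the list alone 33 were lower and 1 higher (median -1.66, adjusted p = 5.52e-33, and adjusted p = 0.496 with an estimated correlation). Cytotoxic genes had 9 of 37 higher, or 32 adjusted over the list alone (median 2.91, adjusted p = 1.13e-30, and adjusted p = 0.496 with an estimated correlation), among them CCL4 at 5.52 ± 0.48, GZMA at 4.84 ± 0.41, the protease inhibitor CST7 at 3.97 ± 0.52 and the T-box factor TBX21 at 3.88 ± 0.52. GZMB at 5.48 ± 1.23 did not pass (adjusted p = 0.147).

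Further genes higher in EM than naive cells were PROK2 at 5.93 ± 0.69, LAIR2 at 5.34 ± 0.46, the phosphatase PTPRM at 4.36 ± 0.19, DUSP5 at 4.22 ± 0.13 and TOX, a factor linked to T cell exhaustion, at 3.40 ± 0.42. The MAIT list had 5 of 31 higher, KLRB1 at 5.73 ± 0.70, IL18RAP at 4.41 ± 0.28, IL18R1, ME1 at 2.94 ± 0.38 and CCR2 at 1.67 ± 0.22, and 18 adjusted over the list alone (median 1.62, adjusted p = 5.87e-15, and adjusted p = 0.600 with an estimated correlation). This median was 1.05 without EM replicate 2. Immediate-early genes had EGR3 at 2.95 ± 0.32 and DUSP2 at 2.17 ± 0.22 higher, with a median of 0.39 (adjusted p = 0.00124, and adjusted p = 0.600 with an estimated correlation), and 7 higher and 2 lower adjusted over the list alone. That median was 0.23 without naive replicate 1 or EM replicate 1, 0.75 without naive replicate 2, 0.77 without EM replicate 2 and 0.26 with the hybridization-control block. NR4A1 and ABCB1 differed by 0.14 ± 0.40 and -0.08 ± 0.37, neither past the threshold. In total 232 genes passed, 132 higher and 100 lower in EM cells, and 112 with the hybridization-control block, of which 80 were shared, and 518 after quantile normalization, 221 of them shared. CCL4, CST7, TBX21, PROK2, LAIR2, TOX, EGR3 and DUSP2 did not pass with the block (adjusted p from 0.0513 to 0.101), nor KLRB1 and ME1 after quantile normalization (adjusted p = 0.0547 and 0.0643). There were 0 without naive replicate 1, EM replicate 1 or EM replicate 2, 5 without naive replicate 2, 23 without TSP replicate 1, 23 without TSP replicate 2, and 0 within the high set.

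Between CM and naive cells limma called 0 genes, against 1506 at an unadjusted p under 0.05 and 19 adjusted after quantile normalization. NOG came closest at -5.46 ± 0.26 (SE, n = 1 and 2 arrays; adjusted p = 0.0651), and it was the 1 gene that passed without TSP replicate 1 or without TSP replicate 2 (adjusted p = 0.0387 in each). IL18RAP was at 3.91 ± 0.34, KLRB1 at 4.53 ± 0.85, CCL4 at 3.23 ± 0.58 and the granzyme GZMK at 3.70 ± 0.70. Cytotoxic genes had a median of 1.62 and naive-associated genes of -0.82 (adjusted p = 1.10e-18 and 1.01e-13), against adjusted p = 0.582 and 0.496 with an estimated correlation. The cytotoxic median was 0.93 with the hybridization-control block. Adjusted over the list alone 15 of 37 and 15 of 40 genes followed these directions, and 2 naive-associated genes were higher. EM and CM cells differed in 1 gene, DUSP5, higher in EM by 3.73 ± 0.16 (adjusted p = 0.0411), against 1022 genes at an unadjusted p under 0.05 and 10 adjusted after quantile normalization, DUSP5 not among them. It did not pass with the hybridization-control block (adjusted p = 0.126) or without any naive, EM or TSP array, when limma called 0 genes. Naive-associated genes had a median of -1.13 between EM and CM (adjusted p = 3.26e-20, and adjusted p = 0.496 with an estimated correlation), with 21 of 40 lower in EM adjusted over the list alone.

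**Figure D3:**
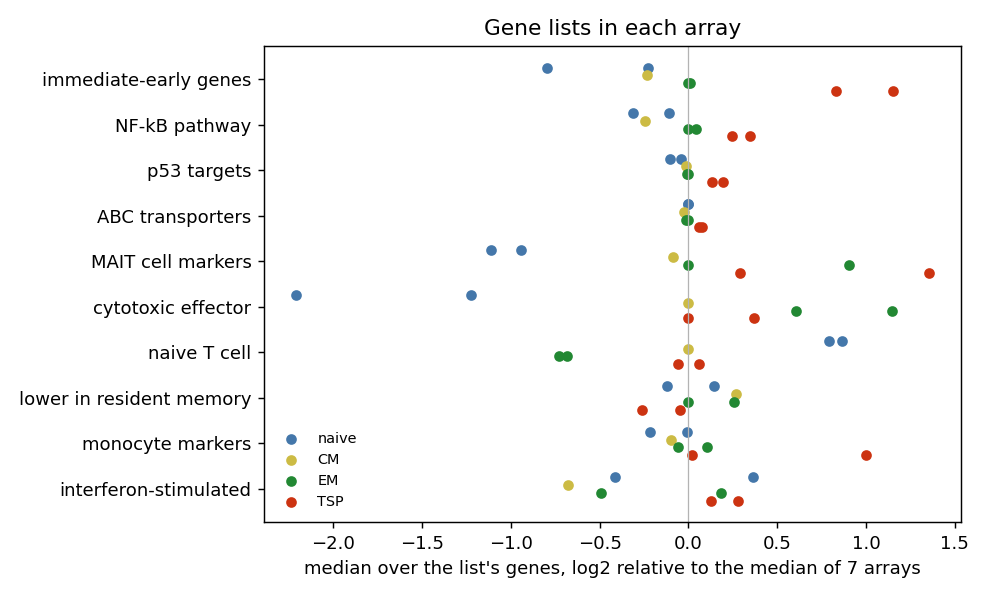
Each point is the median over a gene list's measured members in 1 array, on a log2 scale relative to the median of the 7 arrays, coloured by subset. Immediate-early genes stood at 1.15 and 0.83 in the TSP arrays and at most at 0.007 in the others, and monocyte markers at 1.00 and 0.02 in TSP.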

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

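The tests in this part were chosen after the data were seen. Some calls also stood in probe sets that no comparison above used, those whose annotation gives several gene symbols. Of 1765 such probe sets tested with limma in the same fit, 19 passed between TSP and naive cells, 6 of them higher in TSP. That is a smaller share than the 498 of 19724 genes, each a mean of its probe sets, that passed in this comparison. Because each of these probe sets can read several genes, none is named.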

How the results depend on the processing

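No named gene past the threshold changed direction under any alternative run, while most counts of genes moved. The top genes were named only where the arrays of the 2 groups did not overlap. Leaving out arrays therefore could not reverse them, and their kept direction is no separate support. Blocks or subsets by hybridization control, the robust prior and the crossed pairing were chosen after seeing the data. Counts follow the order TSP against naive, TSP against EM, TSP against CM, EM against naive, CM against naive, EM against CM, and the overlap of the 3 TSP comparisons, with main values of 498, 104, 18, 232, 0, 1 and 14. Quantile normalization gave 275, 67, 32, 518, 19 and 10, with 14 in the overlap. The most variable probe set gave 439, 13, 6, 154, 0 and 0, with 4. All probe sets gave 418, 16, 0, 135, 0 and 0, with 0. Fits of only the groups compared gave 1, 0, 0, 23, 0 and 0, with 0. The hybridization-control block gave 287, 65, 0, 112, 0 and 0, with 0, and the 4 high-set arrays alone gave 0 for TSP against naive, TSP against EM and EM against naive. The robust prior gave 457, 79, 17, 182, 0 and 1, with 13. An unadjusted p under 0.05 with a 2-fold minimum gave 1005, 643, 843, 766, 450 and 280, with 294, and the adjusted p with that minimum 377, 98, 18, 204, 0 and 1, with 14. Leaving out each array in turn gave 0 to 498, 0 to 104, 0 to 2, 0 to 232, 0 to 1 and 0 to 0 genes, and 0 to 2 in the overlap. Leaving out CM changed no count in the comparisons without it, since a lone array adds nothing to the spread. In simulated data without 1 naive array the test for TSP against naive recovered 7.0%, 86.2% and 98.7% of genes changed by 1, 2 and 4. The simulated genes were independent, and the real counts without a naive array fell further than these rates would give. Leaving out an EM array does not alter the difference between TSP and naive means, so that fall came from the estimate of the spread. In the high set alone only the naive group has replicates to give a spread, so its lack of calls says little about that set. For the other changes the cause was not tested.

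Called gene lists numbered 14, 13, 16 and 14 in TSP against naive, EM and CM and in EM against naive, and 0 in each with an estimated correlation. Leaving out each array in turn gave 12 to 15, 8 to 13, 12 to 16 and 14 to 16, the lowest for TSP against EM being without TSP replicate 2, and every other alternative stayed within 1.5 times. Shared replicate numbers were tried as a block with CM left out, giving 18 genes for TSP against naive, 0 for TSP against EM and 49 for EM against naive. Deviations of same-numbered arrays correlated at -0.47 for naive and EM, -0.25 for naive and TSP and 0.37 for EM and TSP. The negative values give no sign that equal numbers pair naive arrays with the others, but they cannot exclude it. Pairing of EM with TSP also stays unresolved. In EM and TSP the number follows the hybridization-control set, so a shared donor and that set cannot be told apart. Crossed pairing of naive numbers with the others, chosen after seeing the data, gave 1232 genes for TSP against naive and 638 for EM against naive. The negative correlations favour such a rise, so it is no evidence of a pairing. The median shift moved nothing, as every array median was already 0, and log2(value + 1) does not apply to log values. The filter on dim probe sets and the intensity trend were not run, because a centred table holds no signal over background.

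Of 173 named values 108 were calls. The robust prior kept 98 of them, quantile normalization 83, the most variable probe set 58, the hybridization-control block 57, the gene's best of all probe sets 52 and fits of only the groups compared 4. Without naive replicate 1 or EM replicate 2 there were 0 left, without EM replicate 1 there was 1, without naive replicate 2 there were 2, and without TSP replicate 1 and 2 there were 14 and 17. Of the 90 calls in comparisons without CM, the replicate block kept 15 and the high set alone 0. Between 169 and 173 of 173 values kept their direction in each setting that gave all 173. For genes named because their arrays did not overlap, this was fixed in advance where arrays were left out.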

Other observations

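All tests in this part were chosen after the results they bear on had been seen. Beyond the genes described above, CCNB1 and PTTG1, which act in mitosis, were higher in TSP than naive cells, at 2.61 ± 0.30 and 2.12 ± 0.28, while MKI67 was at -0.02 and MCM3 was lower at -0.80. The proliferation list of 40 had a median of 0.18 (adjusted p = 0.0125, and adjusted p = 0.617 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. That median was 0.08 without TSP replicate 1 (adjusted p = 0.0498) and 0.07 with the hybridization-control block, and PTTG1 did not pass with the block or after quantile normalization (adjusted p = 0.0734 and 0.0651). Single lipid genes went both ways: the cholesterol synthesis enzyme HMGCS1 was higher in TSP than naive and EM cells, at 1.39 ± 0.11 and 1.10 ± 0.11, and the fatty acid oxidation enzyme CPT2 was lower than in naive cells, at -1.84 ± 0.20. The list of fatty acid and lipid uptake genes had 1 of 27 higher and 1 lower against naive cells, or 5 and 2 adjusted over the list alone. It had no call against naive or EM cells (median 0.10, adjusted p = 0.343, and median 0.03, adjusted p = 0.234). The epoxide hydrolase EPHX2 in TSP lay between the others, at -1.49 ± 0.12 against naive and 1.15 ± 0.12 against EM cells. The endoplasmic reticulum chaperone HSPA5 was higher than in naive and EM cells, at 1.12 ± 0.11 and 1.09 ± 0.11. Against EM cells HMGCS1, EPHX2 and HSPA5 did not pass with the hybridization-control block (adjusted p = 0.0573, 0.0590 and 0.0568), nor HMGCS1 and HSPA5 after quantile normalization (adjusted p = 0.05001 and 0.0607). The heat shock list had no call against naive or EM cells (median 0.07, adjusted p = 0.283, and median 0.20, adjusted p = 0.0894). Against CM cells it was called, with a median of 0.33 (adjusted p = 0.00675, and adjusted p = 0.516 with an estimated correlation), 0 of 20 genes past the threshold, and 1 higher and 1 lower adjusted over the list alone, and its median was 0.52 without TSP replicate 2. It was lower in CM than naive cells (median -0.15, adjusted p = 0.0419, and adjusted p = 0.600 with an estimated correlation), a call lost with the hybridization-control block and without naive replicate 1 (adjusted p = 0.209 and 0.271).

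Immediate-early genes stood higher in both TSP arrays than in the others. A split of the arrays by hybridization controls is argued against as the whole cause for TSP against naive cells. Within the high set, with TSP replicate 2 alone, the median of the 28 genes was 1.55. The lowest of the 3 within-set medians was 1.16 (range 1.16 to 1.55), but it compares TSP with EM. Those subsets each had an array in both sets, so a shift between sets cancels there. Monocyte RNA in TSP replicate 1 is argued against as the whole cause, since in TSP replicate 2 the list lay 1.19 above the naive and EM arrays (quartiles 0.49 to 2.10). In TSP replicate 2 the abundant monocyte transcripts CD14, S100A8 and S100A9 stood at 0, against 1.97, 1.39 and 1.99 in replicate 1, but LYZ and TYROBP stood at 1.05 and 1.19. Incubation at 37 °C with the dye could raise these genes and cannot be told apart from the subset, because 0 arrays outside the TSP group held incubated cells, and a state of TSP cells in the donor stays open and untested.

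Naive-associated genes in TSP lay between naive and EM cells, and TSP cells were not gated on CD45RA or CD45RO. As a list, these genes also lay near the lone CM array. The list median was 0 in CM and 0.06 and -0.06 in the TSP arrays, and the median difference between TSP and CM was -0.15. Centring favours values near 0 in these arrays, since naive lay above and EM below. Single genes differed both ways from CM, with 2 of 40 higher and 3 lower in TSP adjusted over the list alone. A split by hybridization controls is argued against as the whole cause of the difference from naive cells. Within the high set, with TSP replicate 2 alone, the list median for TSP against naive was -1.09. For TSP against EM the within-set medians of the 40 genes were 0.64 and 0.96. Those subsets each had an array in both sets, so a shift between sets cancels there and these medians do not test it. A mixture of naive and EM cells in 1 proportion would give the same naive share from any gene. The median share was 0.26 from 100 genes higher in naive and 0.56 from 132 genes higher in EM cells, a distance of 0.30 (95% bootstrap interval 0.20 to 0.38), and 8 of 8 combinations of single naive, EM and TSP arrays gave one above 0 (0.23 to 0.33). The interval resamples genes as if they were independent. The 8 combinations reuse the same arrays and the genes chosen on them, so neither measures the spread between donors. Within these arrays, the distance argues against such a mixture as the whole cause. A mixture that holds further cell types, such as CM cells, and a separate intermediate subset were not tested and stay open.

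Zinc finger genes, a group of 550 numbered ZNF, ZSCAN, ZKSCAN and ZFP symbols chosen after seeing the data, stood lower in TSP than naive cells, with 417 below 0 (75.8%, against 41.9% of other genes), 28 past the threshold lower and 2 higher. The median was -0.31 (unadjusted camera p = 4.27e-17, and p = 0.0471 with an estimated correlation), and -0.18 against EM (p = 0.0832 with an estimated correlation) and -0.26 against CM cells (p = 0.0592 with an estimated correlation). EM cells, which were not incubated, lay lower too, with a median of -0.08 against naive and -0.09 against CM (unadjusted camera p = 0.000983 and 0.000331, and p = 0.291 and 0.258 with an estimated correlation). Gene length is argued against, because the lowest median of 10000 length-matched random sets was 0.002 and 0 of them were as low. The split by hybridization controls is argued against as the whole cause for TSP against naive cells. Within the high set, with TSP replicate 2 alone, that median was -0.37. The highest within-set median was -0.11 (range -0.37 to -0.11), but it compares TSP with EM, where a shift between sets cancels. Incubation at 37 °C with the dye could account for the larger differences in TSP, and with 0 incubated arrays outside TSP it stays open beside a lower level in TSP cells themselves.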
